A study of Homo sapiens with 48 samples.

How the data were processed

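RNA from MCF-7 cells and from MTF1-null MCF-7 cells was measured in 48 libraries, with 3 replicates in each of 16 groups of genotype and exposure. Cells were plated 48 h before a 6 h exposure to 0.05% DMSO or to 1 of 7 chemicals at 1 to 100 µM. The protocol text speaks of a smaller number of test chemicals, and all 7 that the sample labels name were used. Total RNA was prepared for a targeted human TempO-Seq panel, in which detector oligonucleotides ligated on their target RNA are amplified and sequenced.

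The authors deposited 1 table of counts, with 1 row per probe and 1 column per library, and no normalization was applied to it. Every value is a whole number, the column totals differ between libraries, and 0 counts occur in each deposited column. The processing notes name Bowtie without its version or role. The genome build and the probe manifest behind the counts are not given in the sources used here. Rows are named by gene symbol and probe number, 466 of the 2981 rows share a symbol with another row, and each row was tested on its own. All 48 columns were matched to the sample labels by genotype, chemical and replicate number, and 0 were left out.

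Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 2472 rows and removed 509. TMM factors ranged from 0.876 to 1.22. A quasi-likelihood negative binomial model with robust estimation and 1 mean per group was fitted to all 48 libraries, leaving 32 residual degrees of freedom. The median biological coefficient of variation was 0.253. P-values were two-sided and were adjusted by Benjamini-Hochberg over the tested rows of each comparison, with a call at an adjusted p under 0.05. The 22 comparisons were MTF1-null against wild type in DMSO, each chemical against DMSO in each genotype, and for each chemical the MTF1-null response minus the wild-type response. Standard errors of log2 fold changes came from the same fit. CPM values used effective library sizes. A fitted fold change of a row with counts near 0 in a group depends on the prior count and is no bound. Variation between replicates exceeded counting error in every group, and replicates set the precision. Between 2 libraries of a group the chi-square per degree of freedom was 1.49 for MTF1-null alexidine 1 and 2 and 9.21 to 62.4 for every other pair. Reads amplified by PCR without molecular identifiers are not independent molecules.

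The groups, comparisons, model, gene lists and rule for named genes were fixed before the data were examined. MTF1, if present, and every metallothionein row were to be reported in each comparison. For the wild-type and genotype comparisons, up to 8 rises and 8 falls with the largest changes were taken from called rows whose 3 libraries all lay above, or all below, the 3 controls and whose mean was at least 20 CPM in the higher group. Up to 4 called members of each list with the smallest p were added. For MTF1-null comparisons the numbers were 5 and 3, and for response differences 5 in each direction. A subset of the genes this rule gave is described in the text. Of 122 named symbols, 122 were found in GENCODE 29, which supplied coordinates.

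The 24 gene lists were metallothioneins, other MTF-1 target and zinc transport genes, heat shock response, NRF2 oxidative stress response, ATF4 integrated stress response, endoplasmic reticulum unfolded protein response, cholesterol synthesis and SREBP2 targets, liver X receptor targets, bile acid receptor FXR targets, estrogen response, luminal breast epithelial identity, immediate early genes, p53 targets, NF-kB and inflammatory genes, hypoxia HIF targets, aryl hydrocarbon receptor targets, cell cycle and mitosis, autophagy and lysosome, mitochondrial respiration, housekeeping genes, fibroblast and mesenchymal markers, leukocyte markers, endothelial markers, and basal and other epithelial markers. A list needed at least 3 tested members, and the endothelial list had 1, ENG. The other MTF-1 targets had 6 of 20 given genes tested. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, then with a correlation estimated per list, and with fry, which tests whether a list's genes move on balance one way. Adjustment for lists was over the lists of a comparison, and member counts are given over all rows and adjusted over the list alone.

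Replicate numbers are shared between groups in the labels. In 15 comparisons of 2 groups, deviations from the group means were correlated between libraries of the same number, and the numbers were taken to pair the libraries where every pair had r over 0.1. This held in 8 comparisons, 6 in wild-type and 2 in MTF1-null cells. The fit without a block is the one reported, and the replicate number as block was an alternative.

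The alternatives were RLE scaling, library size alone, no count filter beyond removing rows at 0 everywhere, a mean count of at least 50, counts summed by symbol, the replicate block, DESeq2 1.42.0 on the same rows, only the compared groups in the fit, an estimated correlation or fry for lists, and leaving out each replicate in turn. No library had a total below a set fraction of the median, so the alternative without such libraries was not run, and alternatives for log or normalized values did not apply. A fit without the 5 high-background libraries and a replicate block within genotype were chosen after seeing the data.

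The procedure was tested on negative binomial draws with the means and dispersions of these libraries and known changes. For zinc against DMSO in wild-type cells, edgeR called 46.9% of 98 rows changed 2-fold and 79.6% of 98 changed 4-fold, with 4 false calls among 128. For the zinc response difference it called 22.9% of 96 and 63.3% of 98, with 4 false calls among 88. In both, camera called a list of 20 raised genes and did not call 20 unchanged genes. Draws may lack the high background and shared deviations of real libraries, so these results may not carry over. The other comparisons were not simulated.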

Results

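The transcriptional response to 7 chemicals was measured in MCF-7, a human breast cancer cell line, and in an MTF1-null derivative of it. MTF1 encodes metal-responsive transcription factor 1, which binds zinc and switches on the metallothionein genes. Wild-type and MTF1-null cells were exposed for 6 h to 0.05% DMSO, 100 µM zinc sulfate, 1 µM alexidine, 100 µM astemizole, 30 µM phenoxybenzamine, 10 µM disulfiram, 100 µM deoxycholic acid or 10 µM suloctidil. Each of the 16 combinations of genotype and exposure had 3 replicates, which gave 48 libraries on 1 plate. Expression was read with TempO-Seq. The deposited table held 2981 probe rows for 2735 gene symbols, and 2472 rows had enough counts to be tested. Total counts per library ran from 1085600 to 1602200, with a median of 1368000. The labels do not say whether the replicates were separate cultures, so the p-values may measure technical spread. Values below are log2 fold changes ± SE with n = 3 libraries per group unless another unit is named, and p-values are adjusted over the rows tested in a comparison.

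Libraries within a group were not equally clean. In 5 libraries (wild-type DMSO 1, wild-type zinc 3, MTF1-null zinc 3, MTF1-null astemizole 1 and MTF1-null deoxycholic acid 3) between 0.235% and 2.51% of counts lay in 738 silent rows, whose counts did not exceed 10 in any of the other 43 libraries, where the share was 0.0243% to 0.110%. They are called the 5 high-background libraries, and a number after a group name is its replicate number. Over all exposures, 547 rows differed between wild-type replicate 2 and wild-type replicates 1 and 3 (249 higher, 298 lower). The same test called 10 rows for wild-type replicate 1 and 246 for replicate 3, and 57, 453 and 121 for MTF1-null replicates 1, 2 and 3. These included LOXL1, a lysyl oxidase family member, at 1189 CPM (counts scaled to a common library size) against 140 CPM, and AREG, an epidermal growth factor receptor ligand, at 600 CPM against 2395 CPM. These genes were named after their values were seen. The median of all rows moved by more than 0.1 in some comparisons, to which their fold changes are relative: -0.13 with alexidine, -0.14 with astemizole, -0.13 with phenoxybenzamine and -0.12 with disulfiram in wild-type cells, and 0.12 with astemizole and 0.19 with deoxycholic acid in MTF1-null cells. Among the response differences it was 0.12 for zinc, 0.12 for phenoxybenzamine and 0.15 for deoxycholic acid.

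MTF1 was not analysed here, since no row among those given carries its symbol, and the comparison of unexposed MTF1-null with wild-type cells asked what the loss of MTF-1 changed at rest. The metallothioneins, small cysteine-rich proteins that bind zinc and copper, were the genes examined first. MT1G stood at 476 ± 121 CPM (SD, n = 3) in wild-type and 299 ± 45.3 CPM in MTF1-null cells, and MT2A at 188 ± 57.1 and 144 ± 45.0 CPM. Neither difference passed (-0.67 ± 0.39 and -0.38 ± 0.49, adjusted p = 0.71 and 0.98). MT1X was at 17.6 ± 7.09 CPM in wild-type and 4.53 ± 1.87 CPM in MTF1-null cells, and MT1F had 64, 0 and 8 counts in wild-type and 1, 1 and 2 in MTF1-null libraries. MT1X and MT1F were the ones lower in MTF1-null cells when p was adjusted over the list alone (MT1X -1.97 ± 0.66 and MT1F -4.05 ± 1.40, both adjusted p = 0.022 over the list alone and 0.64 over all rows). The 64 counts of MT1F came from wild-type DMSO 1, a high-background library, so its fitted value rests on that library. MT1X differed by -1.74 ± 0.77 without the 5 high-background libraries. The metallothionein list had a median of -3.17 over its 7 tested members and was lower by the preset test (adjusted p = 0.00050, and adjusted p = 0.41 with an estimated correlation), with adjusted p = 0.030 by the preset test without the 5 high-background libraries. MT1M, MT1E and MT1H, also on the list, had 35, 11 and 20 counts in wild-type DMSO 1 and at most 6 in any other DMSO library. Fibroblast and mesenchymal markers had a median of -1.16 (adjusted p = 0.044, and adjusted p = 0.45 with an estimated correlation). The luminal breast epithelial, autophagy and lysosome and hypoxia lists lay slightly above 0 (medians 0.20, 0.07 and 0.08), with preset adjusted p = 0.022, 0.023 and 0.036. The same lists had adjusted p = 0.45, 0.45 and 0.60 with an estimated correlation.

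Over all genes edgeR called 0 rows different between the genotypes in DMSO and DESeq2 called 0, with 189 rows at an unadjusted p under 0.05 where chance gives 123.6. With a replicate block within genotype, chosen after seeing the data, 5 rows were called (1 higher, 4 lower). Metallothionein probes of similar sequence may share reads, which these data cannot settle, and the metallothionein genes lie together on chromosome 16 (MT2A from 56608199 to MT1X ending at 56684196, GENCODE 29 on GRCh38), while MTF1 lies on chromosome 1.

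Zinc sulfate, the metal that MTF-1 senses, asked which genes respond to zinc and how far the response needs MTF-1. In wild-type cells zinc raised 4 metallothioneins: MT1X rose by 5.40 ± 0.54, adjusted p = 7.7e-09, MT1G by 4.52 ± 0.45, adjusted p = 7.7e-09, MT2A by 4.06 ± 0.54, adjusted p = 5.0e-06 and MT1F by 3.59 ± 0.90, adjusted p = 0.0498. MT1G went from 476 ± 121 to 10958 ± 3326 CPM (SD, n = 3). HMOX1, the heme-degrading enzyme heme oxygenase 1 (chromosome 22, 35380361 to 35394214), rose by 5.05 ± 0.82, adjusted p = 0.00020, and by 4.45 to 5.57 in the refits without 1 library. Of the metallothioneins 4 of 7 rose (4 adjusted over the list alone; adjusted p = 5.8e-37, and adjusted p = 1.4e-07 with an estimated correlation). Heat shock genes rose as a list with 3 of 17 members called (9 adjusted over the list alone; adjusted p = 6.0e-21, and adjusted p = 0.00011 with an estimated correlation). Among them were the cytosolic chaperone HSP90AA1 (1.01 ± 0.16, adjusted p = 0.00014), the mitochondrial chaperonin HSPD1 (0.82 ± 0.14, adjusted p = 0.00048) and the inducible HSPA6 (3.05 ± 0.72, adjusted p = 0.034). The NRF2 oxidative stress list rose too, with HMOX1 and GCLM, a subunit of the glutathione-making enzyme glutamate-cysteine ligase (1.05 ± 0.18, adjusted p = 0.00048), called of 24 tested (5 adjusted over the list alone; adjusted p = 3.0e-15, and adjusted p = 0.00060 with an estimated correlation). Hypoxia targets rose as a list (1 of 16 called, NDRG1 at 2.09 ± 0.50, adjusted p = 0.035; 5 adjusted over the list alone; adjusted p = 9.4e-14, and adjusted p = 0.0030 with an estimated correlation). The glucose transporter SLC2A14 rose by 2.67 ± 0.65, adjusted p = 0.037, though its probe may share reads with SLC2A3. Other MTF-1 target and zinc transport genes had 0 of 6 members called (1 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.14 with an estimated correlation). The ATF4 and immediate early lists rose by the preset test (adjusted p = 2.6e-05 and 0.014) but not with an estimated correlation (adjusted p = 0.25 and 0.74). In all, 15 rows rose and 0 fell in wild-type cells. The count was 9 without DMSO 2 or zinc 3, 8 without zinc 1 and 32 without zinc 2, and 9 without the 5 high-background libraries, 1 of which is zinc replicate 3 and 1 DMSO replicate 1. Refits without 1 library ended the call for MT1F and SLC2A14 (without DMSO 2 or 3 or zinc 1 or 3, highest p 0.29 and 0.30) and HSPA6 and NDRG1 (without DMSO 1, 2 or 3 or zinc 1 or 3, highest p 0.25 and 0.38). The calls for HSPD1, HSPA6 and NDRG1 also ended without the 5 high-background libraries. MT1F rose by 3.08 to 6.06 in the refits without 1 library, the highest without DMSO 1, and by 5.87 without the 5 high-background libraries.

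**Figure D1:**
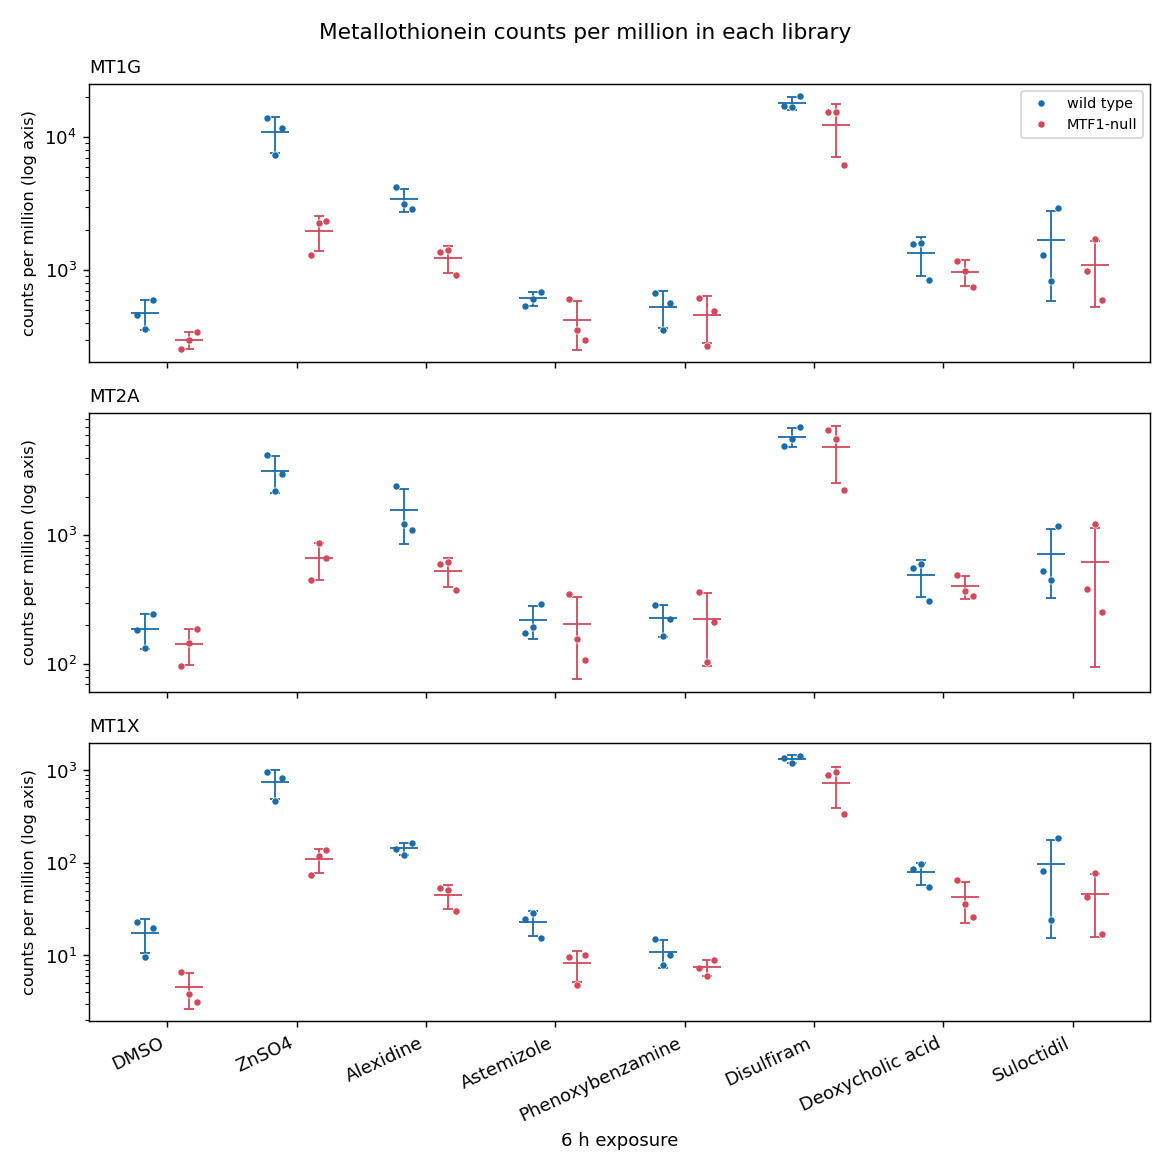
CPM (log axis) of MT1G, MT2A and MT1X in each library after 6 h, by exposure, with wild-type libraries in blue and MTF1-null libraries in red; dots are libraries, long bars the mean and whiskers the SD of 3. With ZnSO4 the mean MT1G level was 10958 in wild-type and 1970 in MTF1-null cells, and with disulfiram 18119 and 12470.

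Zinc still raised metallothioneins in MTF1-null cells, from lower levels. MT1X rose by 4.60 ± 0.61, adjusted p = 1.3e-05 and MT1G by 2.72 ± 0.42, adjusted p = 0.00015, and MT1G went from 299 ± 45.3 to 1970 ± 581 CPM (SD, n = 3). MT2A (2.20 ± 0.50, adjusted p = 0.047) and MT1F (5.59 ± 1.30, adjusted p = 0.047) were also called, the latter from 1, 1 and 2 counts in DMSO to 18, 16 and 195 with zinc. The list rose with 4 of 7 members called and 7 adjusted over the list alone (adjusted p = 2.1e-12, and adjusted p = 0.0029 with an estimated correlation). The remaining calls named here were ORC4, an origin recognition complex subunit (1.55 ± 0.28, adjusted p = 0.0018), and the hypoxia list member SLC2A3 (4.87 ± 1.14, adjusted p = 0.047). The heat shock list had 0 members called of 17 and a median of 0.07 (adjusted p = 0.74, and adjusted p = 0.86 with an estimated correlation). The NRF2 list had 0 of 24 (3 adjusted over the list alone; adjusted p = 0.73, and adjusted p = 0.86 with an estimated correlation). MT1M, MT1E and MT1H, which passed over the list alone, had 98, 34 and 31 counts in zinc replicate 3 and at most 4 in zinc replicates 1 and 2. MTF1-null zinc replicate 3 held 2.51% of its counts in rows silent elsewhere, the most of any library. edgeR called 7 rows higher and 0 lower, with 570 at an unadjusted p under 0.05 and 110 called by DESeq2. Leaving out 1 library gave counts of 3 without DMSO 1, 2 or 3, 369 without zinc 1, 504 without zinc 2 and 2 without zinc 3. Without the 5 high-background libraries 2 rows remained called, MT1X and MT1G. Calls that ended in a refit without 1 library were those for MT2A, MT1F and SLC2A3 (without DMSO 1, 2 or 3 or zinc 3, highest p 0.25, 1 and 1) and ORC4 (without zinc 3, highest p 0.41). In these refits MT1F rose by 3.57 to 6.00 and SLC2A3 by 1.49 to 5.52, the lowest of each without zinc 3.

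MT1G and MT2A, the metallothioneins with the highest counts, rose less with zinc in MTF1-null than in wild-type cells when p was adjusted over the list alone. With zinc, MT1G stood in MTF1-null cells at 18.0% of its wild-type CPM, MT2A at 21.2%, MT1X at 14.6% and HMOX1 at 9.77%. The response of MT1G in MTF1-null minus wild-type cells was -1.81 ± 0.56 (adjusted p = 0.017 over the list alone and 0.10 over all rows) and that of MT2A -1.86 ± 0.69 (adjusted p = 0.037 over the list alone and 0.12 over all rows). MT1X did not pass either test (-0.79 ± 0.86, adjusted p = 0.77), its DMSO level in MTF1-null cells being lower as well. MT1F, MT1M, MT1E and MT1H, near the detection floor in MTF1-null DMSO, had positive fitted values, so the list's median and mean (1.11) lay above 0 while its test pointed down (adjusted p = 0.0548, and adjusted p = 0.45 with an estimated correlation). The heat shock list was lower in the MTF1-null response, with a median of -0.45 and 2 of 17 members lower adjusted over the list alone (adjusted p = 7.9e-09, and adjusted p = 0.035 with an estimated correlation, and adjusted p = 0.11 by fry). The NRF2 and hypoxia lists were lower by the preset test (medians -0.27 and -0.32, adjusted p = 1.2e-05 and 0.00064) but not with an estimated correlation (adjusted p = 0.12 and 0.32). So were the other MTF-1 target genes (adjusted p = 0.013, and adjusted p = 0.14 with an estimated correlation) and the autophagy and lysosome genes (adjusted p = 0.034, and adjusted p = 0.41 with an estimated correlation). The 3 tested bile acid receptor FXR targets, which are liver genes near the floor here, were higher adjusted over the list alone (3 of 3; adjusted p = 0.31, and adjusted p = 0.65 with an estimated correlation). High background was most marked in MTF1-null zinc replicate 3. Over all rows edgeR called 0 for this difference, with 507 at an unadjusted p under 0.05 and 16 called by DESeq2. With a replicate block within genotype, chosen after seeing the data, 2 rows were called, both lower. The count became 164 without wild-type zinc 3, 1 without wild-type zinc 2, 220 without MTF1-null zinc 1 and 368 without MTF1-null zinc 2, and was 0 without the 5 high-background libraries.

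Disulfiram, a dithiocarbamate drug that inhibits aldehyde dehydrogenase, gave the highest mean levels of MT1G, MT2A and MT1X of the 7 exposures in both genotypes. In wild-type cells MT1X rose by 6.22 ± 0.56, adjusted p = 3.4e-10, MT1G by 5.25 ± 0.46, adjusted p = 3.4e-10, MT2A by 4.95 ± 0.56, adjusted p = 1.2e-07 and MT1F by 4.19 ± 0.92, adjusted p = 0.010. MT1G reached 18119 ± 1950 CPM (SD, n = 3). Of the metallothioneins 4 of 7 rose (4 adjusted over the list alone; adjusted p = 5.5e-24, and adjusted p = 1.3e-05 with an estimated correlation). NRF2 targets rose with 7 of 24 called (10 adjusted over the list alone; adjusted p = 5.7e-13, and adjusted p = 0.0024 with an estimated correlation). They included HMOX1 (5.51 ± 0.84, adjusted p = 7.1e-05), GCLM (1.15 ± 0.18, adjusted p = 0.00012) and the thioredoxin reductase TXNRD1 (1.58 ± 0.38, adjusted p = 0.026). Heat shock genes rose with 3 of 17 called (7 adjusted over the list alone; adjusted p = 4.6e-09, and adjusted p = 0.014 with an estimated correlation). These were HSPA6 (4.06 ± 0.73, adjusted p = 0.00070), HSPD1 (0.84 ± 0.14, adjusted p = 0.00032) and HSP90AA1 (0.88 ± 0.16, adjusted p = 0.00074). The hypoxia list rose with 1 of 16 called (4 adjusted over the list alone; adjusted p = 9.7e-08, and adjusted p = 0.0453 with an estimated correlation). The ATF4 list rose by the preset test with 1 of 19 called (5 adjusted over the list alone; adjusted p = 1.1e-06, and adjusted p = 0.17 with an estimated correlation). Of the other MTF-1 target genes 2 of 6 rose, TXNRD1 and GCLC, both also NRF2 list members. The MTF-1 list did not pass (adjusted p = 0.063, and adjusted p = 0.29 with an estimated correlation). Among the 4 rows that fell were the actin-nucleating subunit ARPC3 (-0.85 ± 0.18, adjusted p = 0.0076) and ESR1, the estrogen receptor that marks luminal cells (-0.68 ± 0.17, adjusted p = 0.034). Immediate early genes had an adjusted p = 0.0524 by the preset test (adjusted p = 0.77 with an estimated correlation), and 0.0474 with the replicate number as block. In all 23 rows rose and 4 fell. The count of rows called was 16 without DMSO 1, 14 without DMSO 2 or 3, 42 without disulfiram 2 and 12 without disulfiram 3. With the replicate number as block the count was 49 (35 higher, 14 lower). The refits without 1 library ended the calls for MT1F (without DMSO 2 or 3, highest p 0.078), TXNRD1 and GCLC (each without DMSO 1, 2 or 3 or disulfiram 3, highest p 0.76 and 0.75) and ARPC3 (without DMSO 3 or disulfiram 3, highest p 0.16). They also ended the call for ESR1 (without DMSO 1, 2 or 3 or disulfiram 1 or 3, highest p 0.75). Without the 5 high-background libraries the calls for TXNRD1, GCLC and ESR1 were also lost. With 1 library left out, the rise was 3.68 to 6.67 for MT1F, the highest without DMSO 1, 4.53 to 5.92 for HMOX1, 0.82 to 1.85 for TXNRD1 and 0.74 to 1.55 for GCLC.

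Disulfiram raised metallothioneins and NRF2 targets in MTF1-null cells as well. MT1X rose by 7.34 ± 0.63, adjusted p = 1.2e-10, MT1G by 5.38 ± 0.47, adjusted p = 1.2e-10, MT2A by 5.06 ± 0.57, adjusted p = 7.9e-08 and MT1F by 7.11 ± 1.27, adjusted p = 0.00094. MT1G stood at 12470 ± 5391 CPM (SD, n = 3), 68.8% of the wild-type level. The metallothionein list had 4 of 7 called (5 adjusted over the list alone; adjusted p = 4.9e-26, and adjusted p = 7.1e-06 with an estimated correlation). HMOX1 rose by 4.82 ± 0.82, adjusted p = 0.00048 and HSPA6 by 4.70 ± 0.77, adjusted p = 0.00030. NRF2 targets rose with 5 of 24 called (10 adjusted over the list alone; adjusted p = 3.2e-10, and adjusted p = 0.011 with an estimated correlation). SQSTM1, an autophagy receptor, was among them (1.34 ± 0.29, adjusted p = 0.011). The heat shock, ATF4, immediate early and NF-kB lists rose by the preset test (adjusted p = 0.0038, 6.7e-06, 0.023 and 0.015) but not with an estimated correlation (adjusted p = 0.40, 0.35, 0.68 and 0.68). In all 12 rows rose and 1 fell. The count was 8 without DMSO 1 or 3, 7 without disulfiram 1 and 6 without disulfiram 2. With 1 library left out, the call was lost for SQSTM1 (without DMSO 1 or 3 or disulfiram 1 or 2, highest p 0.26). The MT1G response differed between genotypes by 0.13 ± 0.55 and that of MT2A by 0.11 ± 0.68, both adjusted p = 1, and for MT1G the 95% interval of the difference ran from -0.97 to 1.23. Over all rows edgeR called 0 differences, with 45 at an unadjusted p under 0.05 and 1 called by DESeq2. The heat shock and hypoxia lists were lower in the MTF1-null response by the preset test (medians -0.09 and -0.44, adjusted p = 0.0033 and 0.00012) and the fibroblast markers higher (1.00, adjusted p = 0.027), none of them with an estimated correlation (adjusted p = 0.40 for each).

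Alexidine, a bisbiguanide antiseptic, raised metallothioneins together with stress-response genes. In wild-type cells MT2A rose by 3.06 ± 0.52, adjusted p = 0.00023, MT1X by 3.01 ± 0.51, adjusted p = 0.00023 and MT1G by 2.84 ± 0.42, adjusted p = 3.0e-05. Of the metallothioneins 3 of 7 were called (3 adjusted over the list alone; adjusted p = 3.0e-06, and adjusted p = 0.031 with an estimated correlation). The ATF4 integrated stress response rose with 12 of 19 called (14 higher and 1 lower adjusted over the list alone; adjusted p = 3.6e-21, and adjusted p = 0.0050 with an estimated correlation). They were led by the transcription factor DDIT3 (3.74 ± 0.60, adjusted p = 0.00011), the glutathione-degrading CHAC1 (3.16 ± 0.64, adjusted p = 0.0019), the stress cytokine GDF15 (2.66 ± 0.39, adjusted p = 3.0e-05) and the pseudokinase TRIB3 (2.06 ± 0.27, adjusted p = 2.7e-06). Immediate early genes rose with 6 of 21 called (10 adjusted over the list alone; adjusted p = 2.7e-11, and adjusted p = 0.031 with an estimated correlation). Among them were KLF6 (2.78 ± 0.44, adjusted p = 8.3e-05) and GADD45B (1.39 ± 0.17, adjusted p = 1.3e-06). p53 targets rose with 5 of 23 called (7 adjusted over the list alone; adjusted p = 1.0e-05, and adjusted p = 0.031 with an estimated correlation). Among them were the apoptosis gene BBC3 (2.07 ± 0.35, adjusted p = 0.00024) and GADD45A (1.88 ± 0.35, adjusted p = 0.00081), and GDF15 is on this list as well. NF-kB genes had 3 of 16 called, NFKBIA at 2.23 ± 0.47, adjusted p = 0.0034 (9 higher and 1 lower adjusted over the list alone; adjusted p = 7.4e-07, and adjusted p = 0.13 with an estimated correlation). Cholesterol synthesis genes had 4 of 16 called, the low-density lipoprotein receptor LDLR at 1.45 ± 0.33, adjusted p = 0.0076 (5 adjusted over the list alone; adjusted p = 5.7e-06, and adjusted p = 0.062 with an estimated correlation). Heat shock genes fell by the preset test with 3 of 17 called (4 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.35 with an estimated correlation). Cell cycle genes fell by the preset test with 0 of 54 called (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.00086, and adjusted p = 0.55 with an estimated correlation). The cohesin subunit SMC1A (-1.71 ± 0.30, adjusted p = 0.00027) and cytochrome c, CYCS (-1.07 ± 0.23, adjusted p = 0.0034), fell. In all 57 rows rose and 23 fell. The count of rows called was 37 without DMSO 1 or alexidine 1, 41 without DMSO 2 and 51 without alexidine 3. Refits without 1 library ended the call for LDLR (without DMSO 1 or alexidine 1, highest p 0.058).

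In MTF1-null cells alexidine raised MT1X (3.32 ± 0.62, adjusted p = 0.0018), MT1G (2.05 ± 0.41, adjusted p = 0.0030) and MT2A (1.89 ± 0.50, adjusted p = 0.039). These were 3 of 7 members (3 adjusted over the list alone; adjusted p = 8.6e-08, and adjusted p = 0.016 with an estimated correlation). The ATF4 list rose with 8 of 19 called (12 higher and 1 lower adjusted over the list alone; adjusted p = 3.7e-22, and adjusted p = 0.0039 with an estimated correlation). They included CHAC1 (3.51 ± 0.68, adjusted p = 0.0022), DDIT3 (3.34 ± 0.59, adjusted p = 0.0011), GDF15 (2.09 ± 0.38, adjusted p = 0.0017) and TRIB3 (1.82 ± 0.26, adjusted p = 9.7e-05). Immediate early genes rose with 6 of 21 called (7 adjusted over the list alone; adjusted p = 8.7e-15, and adjusted p = 0.016 with an estimated correlation). KLF6 rose by 2.25 ± 0.43, adjusted p = 0.0019 and GADD45B by 1.03 ± 0.17, adjusted p = 0.00036. p53 targets rose with 4 of 23 called (5 adjusted over the list alone; adjusted p = 4.4e-06, and adjusted p = 0.016 with an estimated correlation), GADD45A at 1.77 ± 0.36, adjusted p = 0.0032. NF-kB genes rose with 2 of 16 called (10 adjusted over the list alone; adjusted p = 7.5e-10, and adjusted p = 0.0485 with an estimated correlation). SMC1A fell (-1.46 ± 0.30, adjusted p = 0.0037), as did the cell cycle phosphatase CDC25A (-1.65 ± 0.39, adjusted p = 0.020). By the preset test alone the heat shock and cell cycle lists fell and the cholesterol list rose (adjusted p = 0.00039, 0.0047 and 0.0014; adjusted p = 0.15, 0.72 and 0.22 with an estimated correlation). In all 29 rows rose and 8 fell, and 58 were called without the 5 high-background libraries. Alexidine 1 and 2 were the closest replicate pair by far and may not be independent samples. The count was 19 without DMSO 1, 2 or 3, 21 without alexidine 1 and 17 without alexidine 2. With the replicate number as block the count was 57 (42 higher, 15 lower). Calls that ended in a refit without 1 library were those for MT2A (without any 1 of the 6, highest p 0.28), SMC1A (without DMSO 2, highest p 0.11) and CDC25A (without DMSO 2 or alexidine 1 or 2, highest p 0.22). The responses differed by -0.79 ± 0.55 in MT1G and -1.18 ± 0.69 in MT2A (adjusted p = 1 for both). For this difference edgeR called 0 rows, with 41 at an unadjusted p under 0.05 and 1 called by DESeq2. The autophagy and lysosome list was lower in the MTF1-null response by the preset test (adjusted p = 0.012, and adjusted p = 0.88 with an estimated correlation).

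Astemizole, a cationic amphiphilic antihistamine, had the most rows called of the 7 exposures in both genotypes, with no metallothionein among them. In wild-type cells MT1G differed from DMSO by 0.37 ± 0.39 and MT2A by 0.23 ± 0.49 (adjusted p = 0.62 and 0.80), and 0 of 7 members rose (0 adjusted over the list alone). The ATF4 list rose with 14 of 19 called (15 higher and 1 lower adjusted over the list alone; adjusted p = 1.4e-26, and adjusted p = 0.0011 with an estimated correlation). They included DDIT3 (4.30 ± 0.61, adjusted p = 5.6e-06), CHAC1 (3.67 ± 0.64, adjusted p = 0.00013), TRIB3 (2.79 ± 0.27, adjusted p = 3.8e-09) and the mitochondrial folate enzyme MTHFD2 (1.73 ± 0.18, adjusted p = 5.5e-09). Cholesterol synthesis genes rose with 12 of 16 called and 1 lower (13 higher and 1 lower adjusted over the list alone; adjusted p = 6.8e-14, and adjusted p = 0.0020 with an estimated correlation). Among them were the rate-limiting HMGCR (1.96 ± 0.33, adjusted p = 8.0e-05), MSMO1 (1.91 ± 0.25, adjusted p = 1.7e-06) and IDI1 (1.60 ± 0.27, adjusted p = 8.9e-05). Endoplasmic reticulum unfolded protein response genes had 5 of 16 called, the chaperone HSPA5 at 1.58 ± 0.22, adjusted p = 4.9e-06 and HERPUD1 at 1.98 ± 0.29, adjusted p = 8.7e-06 (6 adjusted over the list alone; adjusted p = 3.6e-06, and adjusted p = 0.0524 with an estimated correlation). Inflammatory genes had 11 of 16 called, the chemokine CXCL1 at 4.98 ± 0.96, adjusted p = 0.00048 and NFKB2 at 2.43 ± 0.47, adjusted p = 0.00049 (12 adjusted over the list alone; adjusted p = 1.3e-07, and adjusted p = 0.12 with an estimated correlation). Immediate early genes had 9 of 21 called, IER3 at 1.94 ± 0.34, adjusted p = 0.00013 (10 adjusted over the list alone; adjusted p = 4.8e-10, and adjusted p = 0.0524 with an estimated correlation). The cystine transporter SLC7A11 rose by 3.33 ± 0.77, adjusted p = 0.0036 and NFE2L2, which encodes NRF2, by 1.01 ± 0.18, adjusted p = 0.00020. The peroxiredoxin PRDX1 (-1.04 ± 0.16, adjusted p = 1.5e-05) and the glutathione peroxidase GPX2 (-1.62 ± 0.53, adjusted p = 0.0456) fell. The NRF2 list, which holds these 4, moved both ways (adjusted p = 0.74, and adjusted p = 0.99 with an estimated correlation), and the call for GPX2 ended with the replicate number as block (adjusted p = 0.0504). Lysosomal genes such as NPC1, which exports cholesterol from lysosomes (0.86 ± 0.15, adjusted p = 0.00014), and LIPA (0.86 ± 0.15, adjusted p = 0.00014) rose. That list had 3 of 17 called (3 adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.28 with an estimated correlation). The aryl hydrocarbon receptor AHR rose by 1.43 ± 0.26, adjusted p = 0.00024 in a list with 2 of 7 called (adjusted p = 0.0446, and adjusted p = 0.40 with an estimated correlation). p53 targets had 5 of 23 called (5 adjusted over the list alone; adjusted p = 0.0035, and adjusted p = 0.16 with an estimated correlation). Genes that fell included the transcription regulator ID2 (-1.56 ± 0.36, adjusted p = 0.0034), the growth factor BMP4 (-1.16 ± 0.31, adjusted p = 0.012) and NDUFB3, a subunit of respiratory complex I (-1.14 ± 0.20, adjusted p = 0.00013). Mitochondrial respiration genes were lower in 2 of 16 (2 adjusted over the list alone; adjusted p = 0.28, and adjusted p = 0.40 with an estimated correlation). Heat shock and cell cycle genes were lower by the preset test with 3 of 17 and 4 of 54 called (5 and 2 adjusted over the list alone; adjusted p = 0.0035 and 2.2e-05; adjusted p = 0.26 and 0.45 with an estimated correlation). In all 169 rows rose and 63 fell, against 133 and 130 when counts were scaled by library size alone. The count of rows called was 118 without DMSO 1, 143 without DMSO 2 and 98 without astemizole 3. The refits without 1 library ended the calls for GPX2 (without DMSO 1 or astemizole 1, 2 or 3, highest p 0.58). There SLC7A11 rose by 2.81 to 4.99, and GPX2 changed by -1.92 to -0.70, the smallest fall and the highest rise both without DMSO 1. Without the 5 high-background libraries the values were 4.98 and -0.70 (adjusted p = 0.00098 and 0.41).

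Astemizole raised the ATF4, cholesterol, NF-kB, immediate early and unfolded protein response lists in MTF1-null cells. MT1G (0.49 ± 0.39) and MT2A (0.50 ± 0.49) did not pass (adjusted p = 0.56 and 0.65), with 0 of 7 called and 0 adjusted over the list alone. The ATF4 list rose with 14 of 19 called (15 higher and 1 lower adjusted over the list alone; adjusted p = 8.0e-28, and adjusted p = 0.00043 with an estimated correlation). CHAC1 rose by 4.76 ± 0.68, adjusted p = 1.0e-05 and DDIT3 by 4.14 ± 0.61, adjusted p = 1.4e-05. The cholesterol list rose with 12 of 16 called (15 adjusted over the list alone; adjusted p = 1.0e-18, and adjusted p = 0.00043 with an estimated correlation). HMGCR rose by 2.07 ± 0.33, adjusted p = 4.6e-05 and MSMO1 by 1.86 ± 0.25, adjusted p = 4.3e-06. NF-kB genes rose with 13 of 16 called (13 adjusted over the list alone; adjusted p = 7.5e-12, and adjusted p = 0.031 with an estimated correlation). TNFAIP3, which restrains NF-kB signalling, rose by 2.81 ± 0.60, adjusted p = 0.0017 and NFKB2 by 2.17 ± 0.47, adjusted p = 0.0020. Immediate early genes rose with 10 of 21 (12 adjusted over the list alone; adjusted p = 3.4e-14, and adjusted p = 0.017 with an estimated correlation). Unfolded protein response genes rose with 6 of 16 called (6 adjusted over the list alone; adjusted p = 3.2e-06, and adjusted p = 0.031 with an estimated correlation), HERPUD1 at 2.08 ± 0.29, adjusted p = 6.2e-06 and HSPA5 at 1.44 ± 0.22, adjusted p = 3.3e-05. SLC7A11 rose by 3.86 ± 0.80, adjusted p = 0.0013, and PRDX1 fell (-0.74 ± 0.15, adjusted p = 0.0013). NAT1, the arylamine N-acetyltransferase, fell in both of its probes (-1.30 ± 0.33, adjusted p = 0.011 and -1.12 ± 0.26, adjusted p = 0.0039). The heat shock and cell cycle lists were lower by the preset test and the p53 list higher (adjusted p = 0.00033, 1.3e-08 and 0.0022; adjusted p = 0.13, 0.32 and 0.13 with an estimated correlation). In all 144 rows rose and 24 fell. MTF1-null astemizole replicate 1 is among the 5 high-background libraries, without which 130 rows were called and 1 probe of NAT1 lost its call (-1.13, adjusted p = 0.068). Leaving out 1 library gave 68 without DMSO 1, 78 without DMSO 2, 108 without DMSO 3, 109 without astemizole 1 and 69 without astemizole 2. With 1 library left out, the call was lost for NAT1 (without DMSO 2 or astemizole 1 or 2, highest p 0.10). The 2 responses differed by 0.12 ± 0.56 in MT1G and 0.27 ± 0.69 in MT2A (adjusted p = 1 for both). For this difference edgeR called 0 rows different, with 107 at an unadjusted p under 0.05 and 0 called by DESeq2.

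Deoxycholic acid, a secondary bile acid, raised amino acid stress genes and some metallothioneins. In wild-type cells MT1X rose by 2.16 ± 0.51, adjusted p = 0.020 and MT1G by 1.50 ± 0.40, adjusted p = 0.043. These were 2 of 7 members (3 adjusted over the list alone; adjusted p = 0.0039, and adjusted p = 0.30 with an estimated correlation). The ATF4 list rose with 12 of 19 called and 1 lower (14 higher and 1 lower adjusted over the list alone; adjusted p = 2.5e-26, and adjusted p = 0.0012 with an estimated correlation). CHAC1 (3.60 ± 0.64, adjusted p = 0.0025), DDIT3 (3.09 ± 0.58, adjusted p = 0.0033), MTHFD2 (1.55 ± 0.17, adjusted p = 2.8e-07) and the alanyl-tRNA synthetase AARS (1.03 ± 0.20, adjusted p = 0.0033) rose. ATF5, itself a transcription factor of this response, fell (-0.84 ± 0.22, adjusted p = 0.043). Cholesterol synthesis genes rose as a list with 2 of 16 called (10 adjusted over the list alone; adjusted p = 1.5e-10, and adjusted p = 0.010 with an estimated correlation). CYP51A1 rose by 1.04 ± 0.22, adjusted p = 0.0055 and MSMO1 by 1.11 ± 0.25, adjusted p = 0.014. The unfolded protein response gene HERPUD1 rose by 1.41 ± 0.29, adjusted p = 0.0049 (1 of 16 of its list called and 4 adjusted over the list alone; adjusted p = 7.6e-05, and adjusted p = 0.10 with an estimated correlation). ESR1 fell (-0.89 ± 0.17, adjusted p = 0.0033). The immediate early and p53 lists rose and the cell cycle list fell by the preset test (adjusted p = 0.00014, 0.00058 and 1.5e-05; adjusted p = 0.33, 0.10 and 0.58 with an estimated correlation). Of the 3 tested FXR genes, near the floor, 0 were called (adjusted p = 0.47, and adjusted p = 0.83 with an estimated correlation), so FXR activity went untested. In all 28 rows rose and 8 fell. The count of rows called was 17 without DMSO 1, 13 without DMSO 2 and 15 without deoxycholic acid 3. With the replicate number as block the count was 61 (40 higher, 21 lower). Refits without 1 library ended the call for MT1X (without DMSO 1 or 2 or deoxycholic acid 2, highest p 0.13), MT1G (without DMSO 1 or 2 or deoxycholic acid 1 or 2, highest p 0.20) and ATF5 (without DMSO 1, 2 or 3 or deoxycholic acid 2 or 3, highest p 0.53). They also ended the call for MSMO1 (without DMSO 2 or deoxycholic acid 3, highest p 0.094) and ESR1 (without deoxycholic acid 3, highest p 0.13). DDIT3 rose by 2.18 to 3.44 in these refits. Without the 5 high-background libraries the calls for MT1X and MT1G ended as well.

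In MTF1-null cells deoxycholic acid raised MT1X by 3.23 ± 0.62, adjusted p = 0.0041 and MT1G by 1.71 ± 0.40, adjusted p = 0.020. These were 2 of 7 metallothioneins (4 adjusted over the list alone; adjusted p = 2.1e-05, and adjusted p = 0.11 with an estimated correlation). ATF4 genes had 7 of 19 called (12 adjusted over the list alone; adjusted p = 1.3e-10, and adjusted p = 0.11 with an estimated correlation). CHAC1 rose by 4.08 ± 0.68, adjusted p = 0.0015 and MTHFD2 by 0.97 ± 0.17, adjusted p = 0.0017. Cholesterol genes had 1 of 16 called (5 adjusted over the list alone; adjusted p = 1.6e-05, and adjusted p = 0.11 with an estimated correlation). Unfolded protein response genes had 2 of 16 called (5 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.46 with an estimated correlation). The immediate early and NF-kB lists rose and the cell cycle and housekeeping lists fell by the preset test (adjusted p = 0.0015, 0.0025, 3.1e-05 and 0.0082; adjusted p = 0.51, 0.51, 0.54 and 0.20 with an estimated correlation). In all 27 rows rose and 3 fell, against 20 and 12 with RLE scaling. MTF1-null deoxycholic acid replicate 3 is among the 5 high-background libraries, without which 4 rows were called and MT1G and MTHFD2 lost their calls. The count was 4 without DMSO 1, 17 without DMSO 2 and 1 without DMSO 3 or deoxycholic acid 3. Calls that ended in a refit without 1 library were those for MT1X (without DMSO 3, highest p 0.084), MT1G (without any 1 of the 6, highest p 0.22) and CHAC1 (without deoxycholic acid 3, highest p 0.0554). They also ended the call for MTHFD2 (without DMSO 3 or deoxycholic acid 3, highest p 0.33). CHAC1 rose by 3.02 without the 5 high-background libraries. The responses of the genotypes differed by 0.21 ± 0.55 in MT1G and 0.10 ± 0.69 in MT2A (adjusted p = 0.98 and 1). For this difference edgeR called 0 rows, with 289 at an unadjusted p under 0.05 and 1 called by DESeq2. The ATF4 list was lower in the MTF1-null response by the preset test (adjusted p = 0.0050, and adjusted p = 0.70 with an estimated correlation).

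Suloctidil, a cationic amphiphilic vasodilator, moved cholesterol synthesis genes and metallothioneins. In wild-type cells 0 of 16 cholesterol genes passed over all rows and 8 adjusted over the list alone, and the list rose with a median of 0.68 (adjusted p = 4.6e-14, and adjusted p = 0.0036 with an estimated correlation). MT1X (2.43 ± 0.51), MT1G (1.83 ± 0.40) and MT2A (1.93 ± 0.50) rose adjusted over the list alone (adjusted p = 0.00020, 0.00020 and 0.00096) but not over all rows (adjusted p = 0.070, 0.070 and 0.31). The metallothionein list's median was -0.02 and its test pointed up (adjusted p = 0.00019, and adjusted p = 0.18 with an estimated correlation). The ATF4, unfolded protein response and luminal lists lay higher by the preset test (adjusted p = 0.0044, 0.0044 and 0.0081; adjusted p = 0.54, 0.28 and 0.28 with an estimated correlation). edgeR called 0 rows, with 199 at an unadjusted p under 0.05 and 4 called by DESeq2. The count was 0 with the replicate number as block. It was 2 without suloctidil replicate 1 and 3 without suloctidil replicate 2.

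In MTF1-null cells suloctidil raised MT1X (3.34 ± 0.62, adjusted p = 0.0056), MT2A (2.10 ± 0.50, adjusted p = 0.036) and MT1G (1.88 ± 0.40, adjusted p = 0.021). These were 3 of 7 metallothioneins (3 adjusted over the list alone; adjusted p = 3.7e-09, and adjusted p = 0.011 with an estimated correlation). Cholesterol genes rose with 6 of 16 called (13 adjusted over the list alone; adjusted p = 7.5e-33, and adjusted p = 4.6e-06 with an estimated correlation). MSMO1 rose by 1.58 ± 0.25, adjusted p = 0.00067, LDLR by 1.54 ± 0.33, adjusted p = 0.021 and ACLY, which makes cytosolic acetyl-CoA, by 0.87 ± 0.17, adjusted p = 0.0077. The NF-kB list rose with 1 of 16 called (11 adjusted over the list alone; adjusted p = 1.3e-14, and adjusted p = 0.017 with an estimated correlation). The ATF4 list rose with 0 of 19 called (7 adjusted over the list alone; adjusted p = 4.4e-12, and adjusted p = 0.027 with an estimated correlation). The immediate early list rose with 1 of 21 called (2 adjusted over the list alone; adjusted p = 2.6e-11, and adjusted p = 0.028 with an estimated correlation). The unfolded protein response list rose by the preset test and the cell cycle list fell (adjusted p = 0.00068 and 0.0051; adjusted p = 0.14 and 0.76 with an estimated correlation). In all 12 rows rose and 0 fell, with 28 called by DESeq2 and 20 without the 5 high-background libraries. The count was 3 without DMSO 1, 1 without DMSO 2 or suloctidil 2 and 7 without DMSO 3. The refits without 1 library ended the calls for MT1X (without DMSO 2 or suloctidil 2, highest p 0.16), MT2A (without DMSO 1, 2 or 3 or suloctidil 2, highest p 1) and MT1G, LDLR and ACLY (without DMSO 1 or 2 or suloctidil 2, highest p 0.61, 0.67 and 0.12). MT2A rose by 1.15 to 2.46 in them. MT1G differed between the responses by 0.05 ± 0.55 and MT2A by 0.17 ± 0.68 (adjusted p = 1 for both). For this difference edgeR called 0 rows, with 76 at an unadjusted p under 0.05 and 1 called by DESeq2. The NF-kB, cholesterol, immediate early and ATF4 lists were higher in the MTF1-null response by the preset test (adjusted p = 3.3e-06, 0.0020, 0.0017 and 0.0031) but not with an estimated correlation (adjusted p = 0.42, 0.44, 0.67 and 0.68).

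Phenoxybenzamine, an alpha-adrenergic blocker, changed no gene past the test. In wild-type cells MT1G differed from DMSO by 0.16 ± 0.39 and MT2A by 0.27 ± 0.49 (adjusted p = 0.93 and 0.92). In MTF1-null cells they differed by 0.62 ± 0.40 and 0.65 ± 0.49 (adjusted p = 0.95 for both). Of the 7 metallothioneins 0 passed in either genotype, over all rows or adjusted over the list alone. The hypoxia list in wild-type cells had the smallest preset p of the lists (median 0.11; adjusted p = 0.00030, and adjusted p = 0.58 with an estimated correlation). There the autophagy and lysosome list had adjusted p = 0.0492, and adjusted p = 0.58 with an estimated correlation (preset p 0.064 with the replicate number as block). In MTF1-null cells the smallest was that of the ATF4 list (median 0.31; adjusted p = 0.029, and adjusted p = 0.88 with an estimated correlation). edgeR called 0 rows in wild-type cells, with 92 at an unadjusted p under 0.05 and 0 called by DESeq2, and 0 with the replicate number as block. In MTF1-null cells it called 0, with 65 at an unadjusted p under 0.05 and 1 called by DESeq2, and for the response difference 0, with 45 and 0. The MT1G difference between the responses was 0.46 ± 0.56 and that of MT2A 0.38 ± 0.69 (adjusted p = 1 for both).

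**Figure D2:**
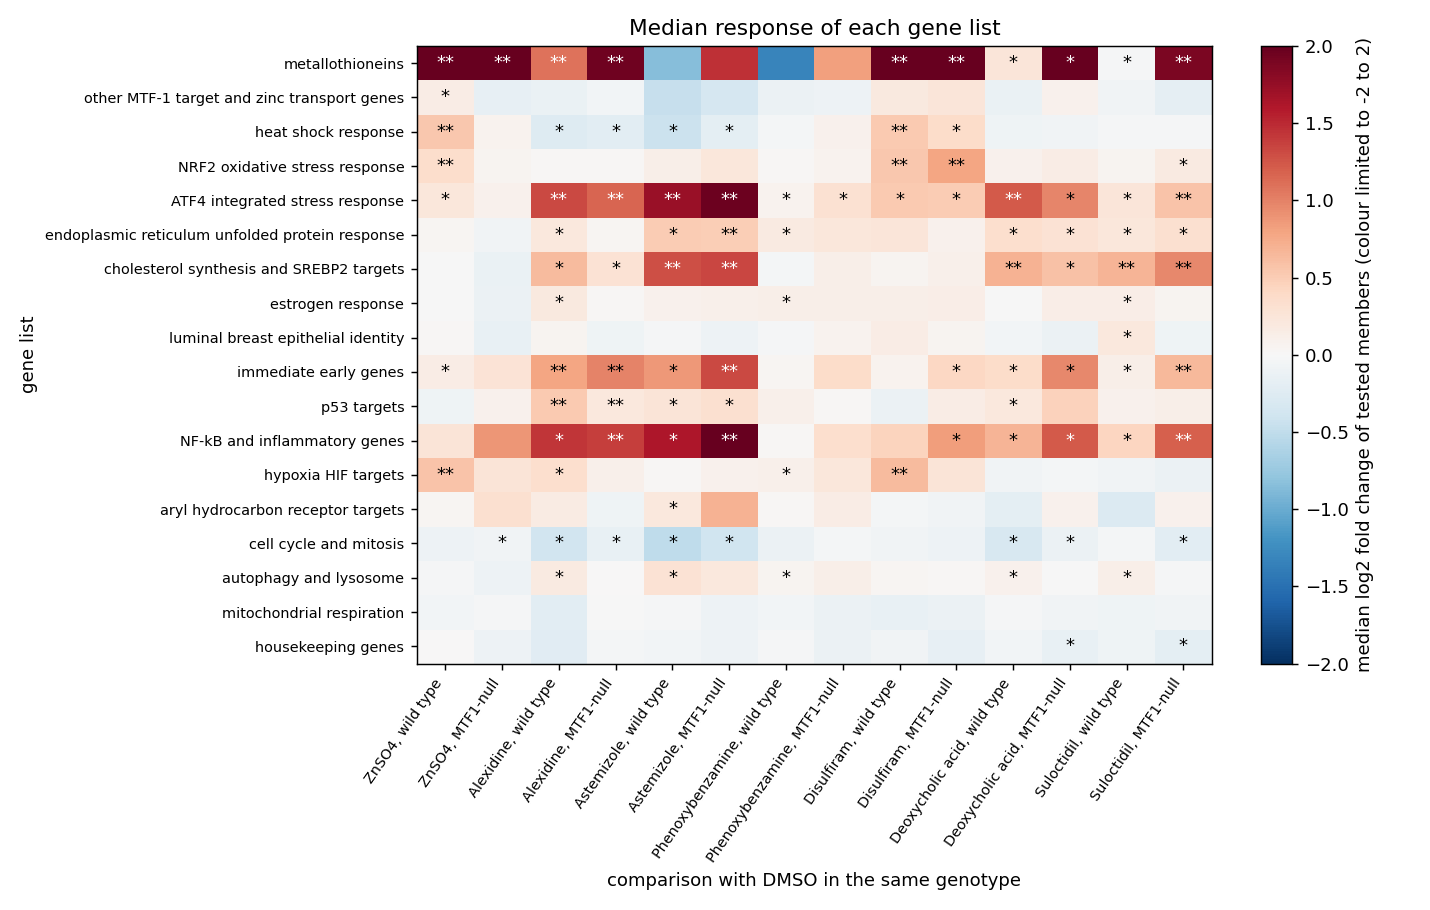
Median log2 fold change (colour) of the tested members of each gene list against DMSO in the same genotype, with 1 asterisk where the list passed with the preset correlation and 2 where it also passed with an estimated one. Metallothioneins, ATF4 targets and cholesterol genes passed most often with an estimated correlation, in 7, 6 and 5 comparisons.

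Across the 22 comparisons, metallothioneins passed with an estimated correlation in 7 and the ATF4 list in 6, and the cholesterol list in 5, immediate early genes in 4, and heat shock, NRF2 and NF-kB genes in 3 each. The hypoxia and p53 lists passed in 2 each and the unfolded protein response in 1. Passed by 0 comparisons with an estimated correlation, with the smallest adjusted p it gave, were the lists of other MTF-1 targets (0.14), mitochondrial respiration (0.13), housekeeping genes (0.20), estrogen response (0.28), luminal identity (0.28), autophagy and lysosome (0.28), cell cycle (0.32), aryl hydrocarbon receptor targets (0.40), fibroblast markers (0.40), liver X receptor targets (0.54), basal and other epithelial markers (0.55), leukocyte markers (0.57) and FXR targets (0.65). The preset test passed estrogen response genes in 3 comparisons, luminal genes in 3, autophagy and lysosome genes in 8, cell cycle genes in 9, housekeeping and fibroblast genes in 2 each and aryl hydrocarbon receptor targets in 1. Mitochondrial respiration, liver X receptor, FXR, leukocyte and basal lists passed it in 0.

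Genes called in both genotypes moved alike, but r over all rows depended on low counts and background. With astemizole 115 rows rose in both genotypes and 17 fell in both, where independent calls would share 9.84 and 0.612. With alexidine 23 rose and 3 fell in both (0.669 and 0.0744 if independent), with deoxycholic acid 15 rose (0.306), with disulfiram 10 (0.112) and with zinc 4 (0.0425), the metallothioneins MT1X, MT1G, MT2A and MT1F. Of the 15 rows that zinc raised in wild-type cells, 15 had the same sign in MTF1-null cells, and of the 7 called in MTF1-null cells 5 had the same sign in wild-type cells. Across all 2472 tested rows Pearson's r between the genotypes' fold changes was -0.68 for zinc, 0.16 for alexidine, -0.26 for astemizole, -0.25 for phenoxybenzamine, -0.13 for disulfiram, -0.67 for deoxycholic acid and -0.19 for suloctidil. Over the 1532 rows with a mean count of at least 50 it was 0.30, 0.72, 0.85, 0.51, 0.80, 0.61 and 0.55, in the same order. The median was 0.61, against a median of 0.34 (-0.36 to 0.70) for the 42 pairs of different chemicals. The same chemical had the highest r for 4 of 7 wild-type responses, and the wild-type zinc response had r = 0.63 with MTF1-null disulfiram. Without the 5 high-background libraries the values over all rows were 0.03, 0.56, 0.46, 0.48, 0.67, 0.57 and 0.45. Rows are not independent replicates, and each chemical's fold changes within a genotype share 3 DMSO libraries.

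**Figure D3:**
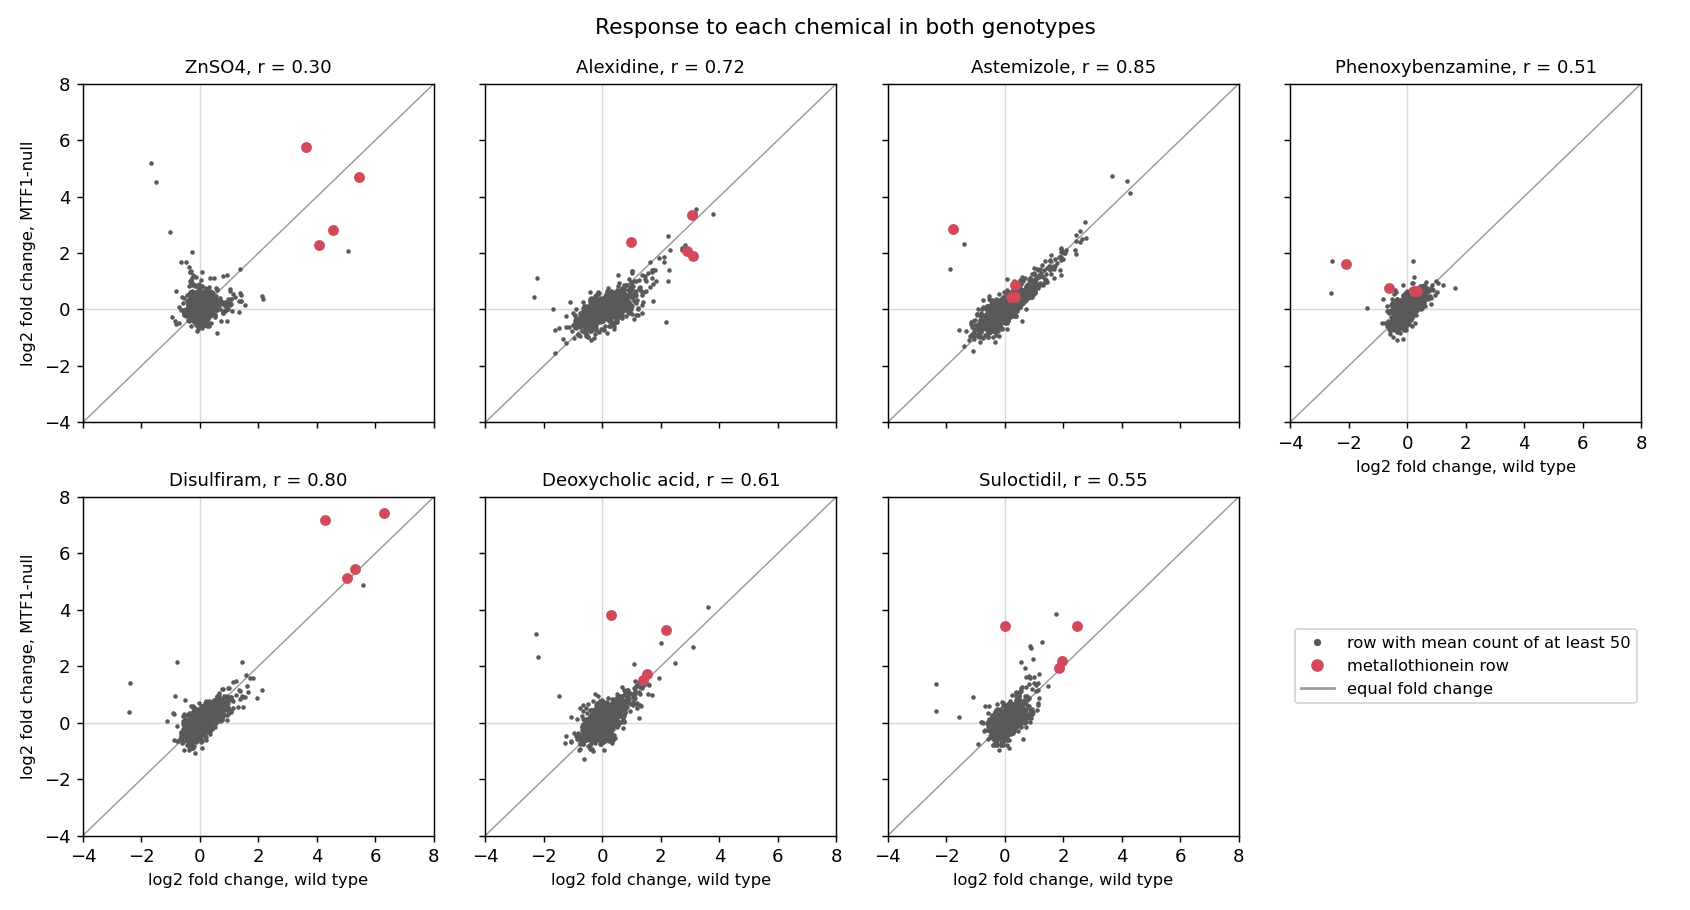
Log2 fold change against DMSO in MTF1-null cells (vertical) and wild-type cells (horizontal) for each chemical, over 1532 rows with a mean count of at least 50, with metallothionein rows in red and a line of equal change. Pearson's r was 0.30 for ZnSO4 and 0.85 for astemizole.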

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

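The tests of explanations in this part and the counts over other splits of the libraries were chosen only after the result was seen. MT1G (-1.81 ± 0.56, adjusted p = 0.017 over the list alone and 0.10 over all rows) and MT2A (-1.86 ± 0.69, adjusted p = 0.037 and 0.12) responded less to zinc in MTF1-null than in wild-type cells, and are given here because the 2 groups differed by a test of the difference itself. The same holds for the heat shock list, whose median difference was -0.45 (adjusted p = 7.9e-09 by the preset test, adjusted p = 0.035 with an estimated correlation and 0.11 by fry).

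High background in 5 libraries is argued against as the whole cause of the smaller metallothionein response, since the MT1G difference was -1.93 ± 0.66 without them. A weaker zinc response of every kind in the MTF1-null wells stays open. So does the loss of MTF-1 itself, which was not tested apart from it. Over the 11 other rows raised by zinc in wild-type cells, the median MTF1-null share of that log2 change was 0.184. It was 0.643 or more with alexidine, astemizole, disulfiram and deoxycholic acid. These rows were picked for their wild-type rise. MT1G and MT2A kept more of theirs (2.72 of 4.52 and 2.20 of 4.06), so the shares cannot decide it.

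Rows below the count filter, which no comparison used, held 1.10% of the counts of MTF1-null zinc 3, above the highest DMSO library (0.306%), and this library is the extreme of the 5 with high background in silent rows. Spillover from the other 43 libraries is argued against, since 90.4% of the silent rows exceeded in that library the highest count of those 43. RNA of another cell type is argued against, since it would bring a few abundant transcripts, and the highest silent row stood 7.71 times above the median silent row, against 252 times among tested rows. Genomic DNA carried into the library stays open and was not tested, since few silent genes have 1 coding exon (12, against 679 with several). CDKN2A, which MCF-7 lacks, was at 0 over the 5 libraries where the median silent row had 70.5 counts.

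Other splits of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Of the 10, 1 gave as many called rows as the real split, itself, for zinc (15 real, 0 the highest other), alexidine (80, 0), astemizole (232, 0), disulfiram (27, 0) and deoxycholic acid (36, 0) in wild-type cells. The same was found in MTF1-null cells for zinc (7, 1), alexidine (37, 0), astemizole (168, 0), disulfiram (13, 0), deoxycholic acid (30, 0) and suloctidil (12, 0). All 10 gave as many, as any split must, where the real count was 0: the genotypes in DMSO and phenoxybenzamine and suloctidil in wild-type cells (highest other 0) and phenoxybenzamine in MTF1-null cells (highest other 380). The split with 380 set MTF1-null DMSO 1, DMSO 2 and phenoxybenzamine 2 against the others, which points to a structure of these libraries. The numbers paired the libraries in 8 comparisons, all but zinc in wild-type and alexidine and suloctidil in MTF1-null cells. The real split parts all 3 pairs, as do 3 of the other splits, and these and the splits that part fewer pairs gave 0 rows in all 8 comparisons. For each response difference 50 splits were drawn and 50 gave at least the real count of 0, as any split must, so the splits leave chance untested there. The highest other was 260 for zinc, 1 for alexidine, disulfiram, deoxycholic acid and suloctidil, and 0 for astemizole and phenoxybenzamine. In zinc 8 splits gave over 100 rows, and 8 of those 8 put both high-background zinc libraries on 1 side.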

How the results depend on the processing

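The fit without the 5 high-background libraries and the replicate block within genotype were chosen only after the results were seen, and the other alternatives were planned. RLE scaling left all 22 counts of called rows within 1.5 times the reported ones, as did the other settings for counts not given below, and the cause of the changes was not tested. With scaling by library size alone the number called was 44 for zinc in MTF1-null cells. With no count filter the number called was 2 for suloctidil in wild-type cells and 3 for zinc, 101 for astemizole and 10 for deoxycholic acid in MTF1-null cells. The sign turned for MT1G astemizole difference (-0.082), MT1G disulfiram difference (-0.0074), MT2A disulfiram difference (-0.029) and MT1G suloctidil difference (-0.086). With a mean count of at least 50 the number called was 125 for alexidine, 45 for disulfiram and 1 for suloctidil in wild-type cells and 25 for suloctidil in MTF1-null cells. Across genes, r between genotypes was 0.30, 0.72, 0.85, 0.51, 0.80, 0.61 and 0.55 for zinc, alexidine, astemizole, phenoxybenzamine, disulfiram, deoxycholic acid and suloctidil. With the replicate number as block the number called was 49 for disulfiram and 61 for deoxycholic acid in wild-type cells and 4 for zinc, 57 for alexidine and 62 for deoxycholic acid in MTF1-null cells. With counts summed by symbol the number called was 2 for suloctidil in wild-type cells. The sign turned for MT1G astemizole difference (-0.0042). With the 5 high-background libraries left out the number called was 9 for zinc in wild-type cells and 2 for zinc, 58 for alexidine, 4 for deoxycholic acid and 20 for suloctidil in MTF1-null cells. Across genes, r between genotypes was 0.027, 0.56, 0.46, 0.48, 0.67, 0.57 and 0.45 for zinc, alexidine, astemizole, phenoxybenzamine, disulfiram, deoxycholic acid and suloctidil. The sign turned for MT2A astemizole response in MTF1-null (-0.16) and MT1G astemizole difference (-0.18). With the replicate block within genotype the number called was 5 between the genotypes in DMSO, 35 for zinc, 166 for alexidine, 385 for astemizole, 83 for disulfiram and 101 for deoxycholic acid in wild-type cells, 3 for zinc, 78 for alexidine, 270 for astemizole, 47 for disulfiram and 100 for deoxycholic acid in MTF1-null cells and 2 for zinc for the response differences. The sign turned for MT2A disulfiram difference (-0.081). With DESeq2 the number called was 23 for zinc, 129 for alexidine, 66 for disulfiram, 64 for deoxycholic acid and 4 for suloctidil in wild-type cells, 110 for zinc, 1 for phenoxybenzamine, 26 for disulfiram, 63 for deoxycholic acid and 28 for suloctidil in MTF1-null cells and 16 for zinc, 1 for alexidine, 1 for disulfiram, 1 for deoxycholic acid and 1 for suloctidil for the response differences. With only the compared groups in the fit the number called was 4 for zinc, 142 for astemizole and 18 for deoxycholic acid in wild-type cells and 2 for zinc, 66 for alexidine, 62 for astemizole, 8 for disulfiram, 0 for deoxycholic acid and 1 for suloctidil in MTF1-null cells.

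Leaving out 1 replicate at a time gave counts of 8 to 32 for zinc, 37 to 63 for alexidine, 98 to 238 for astemizole, 12 to 42 for disulfiram, 13 to 41 for deoxycholic acid and 0 to 3 for suloctidil in wild-type cells. In MTF1-null cells the counts were 2 to 504 for zinc, 17 to 28 for alexidine, 68 to 139 for astemizole, 6 to 14 for disulfiram, 1 to 41 for deoxycholic acid and 1 to 18 for suloctidil, and for the zinc response difference 0 to 368. For r between genotypes the ranges were -0.85 to 0.69 for zinc, -0.082 to 0.32 for alexidine, -0.42 to 0.61 for astemizole, -0.38 to 0.29 for phenoxybenzamine, -0.29 to 0.49 for disulfiram, -0.74 to 0.38 for deoxycholic acid and -0.30 to 0.34 for suloctidil, and the highest value came without wild-type DMSO 1 for zinc, alexidine, astemizole, disulfiram and deoxycholic acid. Signs turned in this way for MT2A astemizole response in wild type (-0.079 to 0.53), MT1G astemizole difference (-0.26 to 0.18), MT1G disulfiram difference (-0.19 to 0.40), MT2A disulfiram difference (-0.26 to 0.39), MT1G deoxycholic acid difference (-0.17 to 0.28), MT1G suloctidil difference (-0.43 to 0.71) and MT2A astemizole response in MTF1-null (-0.16 to 0.64), none of them called in any refit. Leaving out DMSO or zinc 1, 2 or 3 of either genotype moved a count by more than 1.5 times. In wild-type cells the others were alexidine 1 and 3, astemizole 3, disulfiram 2 and 3, deoxycholic acid 3 and suloctidil 1 and 2. In MTF1-null cells they were alexidine 1 and 2, astemizole 1 and 2, disulfiram 1 and 2, deoxycholic acid 3 and suloctidil 2. Of 251 calls for named genes, the number kept was 247 with RLE scaling, 231 with library size alone, 198 without a count filter, 209 of 212 with a mean count of at least 50, 229 with counts summed by symbol, 250 with DESeq2, 248 with the replicate block, 247 with the block within genotype, 152 of 248 with only the compared groups and 186 without the 5 high-background libraries, and 0 turned sign. In 39 refits without 1 library, 1019 of 1506 calls were kept, 0 turned sign, and 115 of the 251 were never lost. The replicate block ended the calls for MT2A (2.20, adjusted p = 0.050028) and SLC2A3 (4.71, adjusted p = 0.0522) with zinc in MTF1-null cells, where numbers did not pair the libraries, and for GPX2 with astemizole, and no other call of a named gene. It ended the call of the autophagy list with phenoxybenzamine in wild-type cells and added that of the immediate early list with disulfiram. Of 120 list calls, 36 held with an estimated correlation and 53 were shared with the 55 of fry, and 118, 117, 117, 87, 119, 116 and 95 with RLE scaling, library size alone, no filter, a mean count of at least 50, the replicate block, summed counts and without the 5 high-background libraries. The list tests passed 99 to 147 times in the refits without 1 library. With 3 libraries per group, rows near the detection floor had wide standard errors, 2.43 (log2) for MT1M and 2.14 for MT1E between the genotypes, which limits what their comparisons can show.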

Other observations

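The comparison of replicate numbers and all tests of explanations in this part were chosen only after the result was seen. Wild-type replicate 2, averaged over the 8 exposures, was set against replicates 1 and 3. It had higher LOXL1 (3.08 ± 0.11), the keratin KRT6A (2.67 ± 0.16) and CAV1 (2.18 ± 0.09). PRSS2 (-3.32 ± 0.34), AREG (-1.93 ± 0.20) and S100A9 (-1.85 ± 0.36) were lower. If a number is 1 culture, SEs and calls here rest on spread among its wells. The basal and other epithelial list was higher, with 2 of 5 members called (adjusted p = 0.00055, and adjusted p = 0.0085 with an estimated correlation), and 12 of 54 cell cycle genes rose (adjusted p = 0.00033, and adjusted p = 0.74 with an estimated correlation). MTF1-null replicate 2 differed from replicates 1 and 3 in 453 rows, and the higher ones included IFI27 (1.91 ± 0.35), DDX60 (1.74 ± 0.22), IFI6 (1.32 ± 0.24) and IFIT1 (1.23 ± 0.28). IFI27 was also higher in wild-type replicate 2 (1.65 ± 0.38). In MTF1-null replicate 2, 17 of 54 cell cycle genes fell and 3 rose (adjusted p = 0.00082, and adjusted p = 0.57 with an estimated correlation). These genes were named after their values were seen, and 48 rows were called in the same direction in replicate 2 of both genotypes, where independent calls would share 49.5.

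A handling batch shared by replicate 2 of both genotypes is argued against as the cause of the wild-type difference, since over its 547 rows the median MTF1-null change in the wild-type direction was 0.028 with an upper quartile of 0.25, against a median wild-type size of 0.53. Other cells mixed into the replicate-2 culture are argued against as the cause of the lower rows, since the median of the luminal list (2 of 12 members rose and 2 fell) was -0.0068 while 17 well counted rows lay below 0.5 of their level. The share of counts in silent rows cannot be told apart from that of the other wild-type libraries (highest 0.0637% in wild-type replicate 2, median 0.0564% in the others). A test added after that share was seen cannot decide on background as the source of the higher rows. Of these 249, 226 were higher by more than the 7.22 CPM of the highest silent row in replicate 2. The choice of silent rows caps that row at 10 counts. The rule also counted the 298 lower rows, which gave 95.8% of the 547. Lower rows cannot either, since replicates 1 and 3 include high-background wild-type DMSO 1 and zinc 3. A small share of other cells as the source of the higher rows, such as those of the basal list, and a separate stock or passage for each number stay open and were not tested.

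Across 1532 well counted rows, 41 of 48 libraries deviated from their group most like the libraries of their own replicate number in the other groups of their genotype, 21 of 24 in wild-type and 20 of 24 in MTF1-null cells, and 16 of 16 of those numbered 2. Wild-type zinc 1 correlated best with number 3 (r = 0.74 across genes) and wild-type zinc 3 with number 1 (r = 0.69 across genes), and genes are not independent replicates. An exchange of numbers 1 and 3 in wild-type zinc was not tested. As labelled, wild-type zinc was not among the 8 paired comparisons (r with the DMSO library of the same number -0.49 for number 1 and -0.61 for number 3). That count and the fits with a replicate block rest on the numbers as labelled.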
